A study of Mus musculus with 2 samples.

How the data were processed

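The series holds single-cell RNA-seq of adult mouse lungs after ablation of alveolar type 2 (AT2) cells and of control lungs, with 1 library in each group. Per the labels, Sftpc-CreER;Rosa26R-DTA mice, in which a Cre recombinase driven by the surfactant protein C gene turns on diphtheria toxin A, received tamoxifen on 3 consecutive days, and lungs were taken 3 days after the last dose. The genotype label of the control library is wild type, while its treatment text is word for word that of the ablation library, so the labels leave open whether the control mice received tamoxifen. Lungs were digested with collagenase, dispase and DNase. Per the labels' protocols, the ablation library pooled 11200 cells depleted of CD31, CD45 and CD140a with 3200 CD45-depleted and 1600 undepleted cells, and the control library was depleted of CD31 and CD45 only. CD31 marks endothelium, CD45 leukocytes and CD140a, the product of Pdgfra, fibroblasts, so these steps set the shares of endothelial, immune and fibroblast cells, and none of the antibodies is aimed at epithelium.

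The libraries were made with 10x Genomics Chromium v3.1 chemistry per the labels, and reads were processed with Cell Ranger 3.0.0 against mm10 (GRCm38) per the submitters' processing notes. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode in the filtered matrices, which were read as whole numbers with no further scaling. The files list 32285 genes, of which 32158 gene identifiers were found in the GENCODE vM21 name table, from which the coordinates given in the text come. The lowest total per barcode was 500 UMIs in both libraries.

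Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which left 10404 of 12860 ablation barcodes and 6648 of 12589 control barcodes. In the ablation library 11.3% of barcodes lay under 1000 UMIs, against 43.1% in control. Doublets were scored with scrublet in scanpy 1.11.5 at an expected rate of 5%. Its automatic threshold was 0.638 in the ablation library, where it called 1 cell, and 0.160 in control, so the control's threshold was applied to both libraries, a choice made after seeing the data. This removed 434 ablation cells (4.17%) and 420 control cells (6.32%) and kept 9970 and 6228 cells.

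Kept cells of both libraries were scaled to 10000 UMIs per cell and log-transformed. They were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1 (igraph 0.11.9, seed 0). No integration across libraries was used because library and condition are the same thing. A cluster took the name of the cell type whose markers, of 30 fixed marker sets, had the highest mean log2 fold over the other cells. At least 3 of these markers had to be at least 1.0 log2 unit above the other cells and present in at least 10% of its cells, at least 1 had to be among the 10 top genes of the cluster, and no other set could have more genes among those 10. Clusters 1, 10 and 21 and epithelial cluster 5 had enough markers but stayed unnamed by the condition on top genes. The epithelial clusters were clustered again at resolution 0.5. Names carry the suffix -like, and clusters that earned no name are given by number. Genes that name a cluster are not results about it.

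Within each class with at least 50 cells in each library, UMIs were summed by library and given as CPM of the class. Sums carry exact Poisson 95% intervals, ratios of CPM exact conditional binomial intervals, and shares of cells exact Clopper-Pearson intervals. Where a share is 0, the upper limit given is 3 cells over the total, which is lower than the 2-sided Clopper-Pearson limit. All of these cover counting error only and say nothing on differences between animals. With 1 library per group no test between groups was run, and a gene was called higher or lower in the ablation library by size alone, at a CPM ratio of at least 1.5 (0.58 on the log2 scale). Where a library held no UMI of a gene, the fold is a lower bound computed against 3 UMIs.

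The 27 gene lists, fixed before the data were examined along with the marker sets and the naming rule, were AT2 identity, AT1 identity, alveolar transitional state, club identity, inflammation-primed AT2, surfactant lipid synthesis, cholesterol synthesis, p53 targets, cell cycle, YAP TEAD targets, TGF-beta targets, EGF family ligands, cytoskeleton and adhesion, interferon response, NF-kB inflammation, MHC class II, unfolded protein response, dissociation and immediate early, hypoxia and glycolysis, Notch, Wnt, alveolar niche factors, matrix and fibrosis, capillary repair, macrophage phagocytosis, type 2 response and translation factors. For each list the median log2 ratio over members with at least 10 UMIs in the class is given with its order-statistic interval and its percentile among 10000 random lists of the same size, matched on expression in 20 bins. The percentile describes these 2 libraries and is not a p-value. The lists of AT2, AT1, transitional and club genes overlap the marker sets that name these classes.

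Named genes are the 10 highest and 10 lowest in the AT2-like and AT1-like classes and the 5 highest and 5 lowest in other classes, ranked by log2 ratio with 10 CPM added to both values. They had a UMI in at least 10% of cells of the class in the library where they were higher, and a CPM in the class there at or above that of all kept cells. Mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, sex-linked genes and unnamed gene models were left out. For each list the members with the largest and smallest ratios among those with at least 50 UMIs were named, and Sftpc, Sftpb, Hopx, Ager, Krt8, Cdkn1a, Scgb1a1, Mki67, Pdgfra, Pecam1 and Ptprc served as checks of the labels and the depletions.

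To even out depth, every cell was also thinned at random to 1000 UMIs, and shares of cells with a UMI are from thinned cells unless stated. Because free RNA in droplets adds UMIs to cells that do not express a gene, such shares stand beside the share in pericyte-like cells. This is a background level only for genes that pericytes lack, which was not checked for each gene. Median UMIs per cell of the pericyte-like class were 2228.5 in the ablation library and 6526 in control.

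The fixed alternatives were a loose filter (200 genes, 25% mitochondrial), a strict filter (1000 genes, 2000 UMIs, 10%), doublet calls kept, coarser (0.5 and 0.3) and finer (2 and 1) clusters, libraries clustered apart, clustering without the alveolar lists, median-of-ratios scaling, totals without AT2 identity and mitochondrial genes, thinned cells, a minimum of 50 UMIs per list member, pseudocounts of 1 and 50 CPM and a detection minimum of 5%. Alternatives chosen after seeing the data were scrublet's automatic threshold in each library, the removal of cells whose share of UMIs in their own class's markers lay under 25% of the class median, the removal of cells with at least 10% of another compartment's marker share, the removal of control cells with a Xist UMI, and totals without Scgb1a1. The rule on another compartment's markers was tried first and removed most alveolar cells.

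The measures were tested on simulated data, Poisson draws from the mean profile of both libraries of a class with 200 genes altered, 100 of them 2-fold and 100 of them 4-fold, which hold counting error only. In the AT2-like class 96% of the genes altered 2-fold and 99% of those altered 4-fold came out beyond 1.5-fold in the right direction, and intervals held the true value for 99%, 93% and, among unaltered genes, 96.3%. The AT1-like class gave 93% and 100%, with intervals that held the true value for 96%, 97% and 96.4%. Computations used Python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.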

Results

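Single-cell transcriptomes were collected from lungs of adult mice 3 days after the last of 3 daily tamoxifen doses that turn on diphtheria toxin A in Sftpc-expressing cells, and from control lungs. Each group had 1 library, so every comparison is of 1 library with 1 library and no replicate error could be computed. The ablation library held 87999426 UMIs over 12860 barcodes and the control library 93805241 UMIs over 12589 barcodes. After filtering, 9970 ablation cells with a median of 5335 UMIs and 2064 genes and 6228 control cells with a median of 9554 UMIs and 3154.5 genes remained. Bracketed ranges are exact 95% intervals for counting error only, and log2 ratios are ablation over control.

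Sftpc (ENSMUSG00000022097, GRCm38 chromosome 14, 70520949 to 70524081), the surfactant gene that drives the Cre transgene, stood at 3646 CPM over all kept ablation cells and 36478 CPM in control, 10.0-fold lower. Sftpb was 3.21-fold lower over all kept cells (688 against 2208 CPM), and the AT1 genes Hopx (134 against 615 CPM) and Ager (283 against 1487 CPM) were 4.599-fold and 5.26-fold lower. The endothelial gene Pecam1 was 51.2-fold higher in the ablation library (130 against 2.53 CPM) and the leukocyte gene Ptprc 484-fold higher (172 against 0.356 CPM). The ablation pool held 3200 CD45-depleted and 1600 undepleted cells, whereas control was depleted of CD31 and CD45. Pdgfra, the gene of CD140a, was 1.52-fold lower (268 against 406 CPM). Alveolar fibroblast-like cells made up 15 cells (0.150%) of the ablation library and 3155 cells (50.7%) of control, and capillary endothelial-like cells 958 cells (9.61%) and 0. A further 932 ablation and 8 control cells formed cluster 0, and 710 ablation cells and 1 control cell formed cluster 10. Both clusters were closest to alveolar fibroblasts but earned no name. Shares of all cells were therefore not compared, and composition was compared among epithelial cells.

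The comparison of epithelial composition asks which epithelial cells were present after the ablation. Of 756 epithelial cells in the ablation library 212 were AT2-like, 28.0% [24.9, 31.4], against 488 of 1799 in control, 27.1% [25.1, 29.2], so no difference in this share was detectable. AT1-like cells, the thin gas exchange cells, made up 26.3% [23.2, 29.6] (199 cells) against 50.7% [48.4, 53.03] (912 cells). Ciliated-like cells made up 31.0% [27.7, 34.4] (234 cells) against 8.004% [6.79, 9.36] (144 cells). Transitional-like cells, named by 11 of 16 markers of the state between AT2 and AT1 cells, made up 40 ablation cells, 5.29% [3.81, 7.14], and 0 of 1799 control cells, which allows a share of up to 0.167%. The name rests on these markers alone. The AT1 genes Hopx and Ager were lower in these cells than in AT2-like ablation cells. Whether the cells were on the way from AT2 to AT1 was not tested. Club or secretory-like cells made up 9.13% [7.17, 11.4] (69 cells) against 13.8% [12.2, 15.5] (248 cells), but this direction turned under 7 of 11 alternatives, for example to 13.1% against 4.73% under the strict filter and 8.94% against 1.02% with coarser clusters. Basal-like cells numbered 2 and 7.

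**Figure D1:**
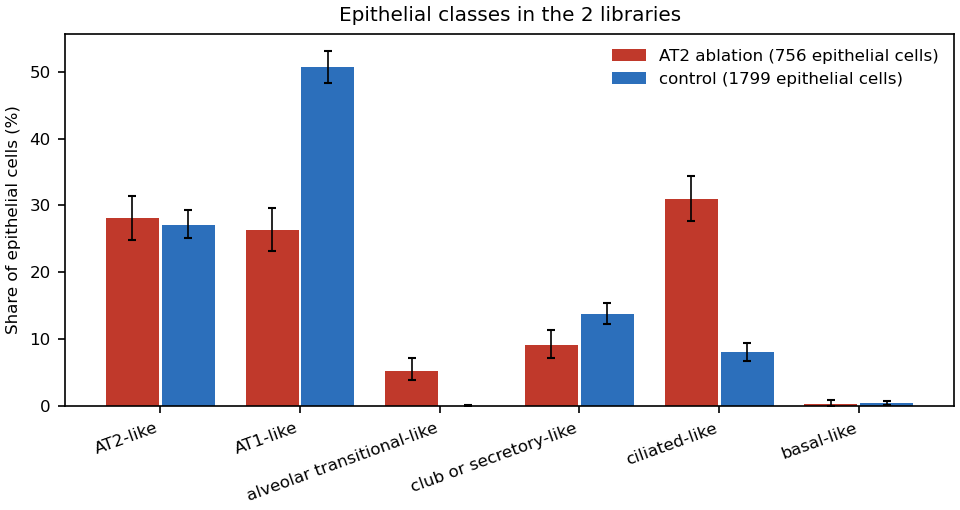
Share of epithelial cells (percent) in each class in the ablation and the control library, with exact 95% intervals for counting error. AT2-like shares were 28.0% and 27.1%, AT1-like 26.3% and 50.7%, ciliated-like 31.0% and 8.004%, and transitional-like 5.29% and 0.

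Set against ciliated-like cells, which the transgene is not aimed at, AT2-like cells were 3.74-fold fewer in the ablation library, at 0.906 [0.749, 1.10] per ciliated-like cell against 3.39 [2.81, 4.11]. AT1-like cells were 7.45-fold fewer on the same scale, at 0.850 [0.7004, 1.03] against 6.33 [5.31, 7.60]. There were 1.07 [0.874, 1.30] AT2-like cells per AT1-like cell in the ablation library and 0.535 [0.478, 0.598] in control. Per club-like cell the direction of AT2-like cells was the opposite, at 3.07 [2.33, 4.09] against 1.97 [1.69, 2.30]. Under the strict filter it was 2.49 [1.87, 3.33] against 7.94 [5.98, 10.7], so the result depends on the reference class and the filter. These ratios depend on which low-UMI barcodes are kept. With the loose filter 4033 control barcodes were named ciliated-like and the direction turned, at 0.850 [0.724, 0.997] AT2-like cells per ciliated-like cell against 0.145 [0.132, 0.158], while under the strict filter the values were 1.09 [0.878, 1.37] against 3.90 [3.16, 4.85]. The loose filter also turned the AT1-like share (35.3% against 25.1%) and set the AT2-like share at 24.8% against 9.40%, and the strict filter set the latter at 32.5% against 37.6%. Without cells that carried another compartment's markers, a rule that removed most alveolar cells, the AT2-like share was 40.2% against 90.6% and the AT1-like share 8.84% against 4.71%.

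Within AT2-like cells the comparison asks how the AT2 cells found after ablation differed from those of control lungs. Cell cycle genes were higher in the ablation library, 18 of 18 members, with a median log2 ratio of 2.18 [1.73, 2.70], above all of 10000 random lists. Pclaf, a clamp-binding factor of DNA replication, stood at 54.7 against 5.05 CPM (3.44 [3.05, 3.83]) and Cdc20, an activator of the anaphase-promoting complex, at 111.7 against 13.02 CPM (3.1002 [2.85, 3.35]), while Pcna (0.64) and Mki67 (1.004 [0.78, 1.22]; 67.8 against 33.8 CPM; chromosome 7, 135689784 to 135716361) had the smallest ratios. After thinning, 71 of 212 ablation AT2-like cells, 33.5% [27.2, 40.3], held a UMI of the cell cycle list, against 49 of 488, 10.0% [7.52, 13.1], in control. Pericyte-like cells gave 9.01% and 12.6%, AT1-like cells 10.6% and 7.46%. With at least 2 such UMIs the AT2-like shares were 16.5% and 2.46%. The cell cycle median was 2.62 in thinned cells, 5.88 with the libraries clustered apart, and Mki67 stood at −0.16 with finer clusters.

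Genes of the transitional state were also higher in AT2-like cells, 12 of 16 with a median of 1.36 [0.44, 2.36] (0.87 thinned, and 0.75 without 18 ablation and 6 control cells low in AT2 markers). The urokinase receptor gene Plaur stood at 27.6 against 0.930 CPM (4.89) and Sprr1a, of the cornified envelope, at 48.5 against 5.05 CPM (3.26), while Areg was lower (142 against 293 CPM, −1.05). Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482) stood at 645 [620, 671] against 314 [305, 323] CPM, a log2 ratio of 1.04 [0.97, 1.11]. Krt8 UMIs were found in 34.0% [27.6, 40.8] of thinned ablation cells and 22.3% [18.7, 26.3] of thinned control cells, against 1.20% and 5.56% of pericyte-like cells. Unthinned shares were 81.6% and 94.3%. Cdkn1a, the p21 cell cycle inhibitor, stood at 215 against 105 CPM (1.04), with thinned shares of 16.5% and 6.35%, against 13.8% and 13.4% of pericyte-like cells. Pericyte-like cells may express Cdkn1a themselves, so their shares are not read as a background level. Of the p53 targets 7 of 15 were higher and 1 lower (median 0.52, percentile 91.2), with Phlda3 at 2.09 and Aen at 1.62.

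Genes of the inflammation-primed AT2 list were higher in AT2-like cells, 8 of 10 members (median 1.499 [0.36, 2.94], percentile 100). Orm1, an acute-phase glycoprotein, stood at 84.1 against 11.0 CPM (2.94), and Retnla was lower (−0.62). Saa3 stood at 160 against 13.4 CPM (3.58), but 2 cells held 88.7% of its ablation UMIs. Of interferon response genes 11 of 16 were higher (median 1.32 [0.48, 3.14]), and the median was 0.30 without the cells low in AT2 markers. The top member Isg15, at 236 against 5.38 CPM, had 86.6% of its ablation UMIs in 2 cells. Unfolded protein response genes were higher in 9 of 14 cases (median 1.06 [−0.54, 1.79], percentile 100), with Sdf2l1, an endoplasmic reticulum chaperone cofactor, at 75.1 against 9.10 CPM (3.04) and Chac1 at 13.9 against 0.266 CPM (5.71 [4.27, 7.64], 4 control UMIs). Type 2 response genes were higher in 8 of 10 cases (1.51, percentile 99.99). Among them Chil3 (285 UMIs against 0) and Ccl24 (167 UMIs against 0) had 92.3% and 100% of their ablation UMIs in 2 cells. Chil3 and Mrc1 were also top genes of alveolar macrophage-like cells (344 ablation and 0 control cells). Ccl24 and Arg1 were top genes of interstitial macrophage-like cells (526 and 1), and Ccl17 of dendritic cell-like cells (205 and 0). Free RNA or doublets of such cells could thus reach almost only ablation droplets, and their part in this list was not tested.

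Immediate early and heat shock genes (the dissociation and immediate early list) were lower in ablation AT2-like cells, 13 of 18 with none higher. Their median was −1.45 [−2.62, −0.57], below all random lists. The libraries differed in depletion and pooling, so a difference in tissue handling cannot be told apart from one due to the ablation. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) stood at 186 against 1604 CPM (−3.11 [−3.22, −3.00]) and Fosb at 56.7 against 679.9 CPM (−3.58). UMIs of Fos were found in 13.2% and 66.8% of thinned AT2-like cells and in 33.2% and 94.9% of pericyte-like cells. The pericyte-like shares were the higher ones in both libraries, so they are not read as a background level for Fos. MHC class II genes, which AT2 cells express, were lower in 4 of 7 cases (−0.63 [−0.93, −0.031], percentile 0.285), with H2-Ab1 at −0.93. TGF-beta targets were lower in 7 of 13 cases and higher in 5 (median −1.03, percentile 0), with Bhlhe40 at −1.91, Tgfb2 at 1.52 and Tgfbi at 1.29. That median was 0.20 with the loose filter, 0.17 with the libraries clustered apart and 0.069 with coarser clusters.

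AT2 identity genes, which name the class, had a median of 0.083 [−0.18, 0.45] (percentile 9.22), with 2 of 14 higher and 2 lower. Sftpc itself was lower, at 59927 against 168769 CPM (−1.49), and Chil1 at −0.72, while the complement gene Hc (992 against 251 CPM, 1.98) and the chemokine gene Cxcl15 (13181 against 6351 CPM, 1.05) were higher. Sftpc drives the Cre transgene. Lower expression thus cannot be told apart from an effect of the transgene on this gene or on which AT2 cells remained. Sftpb stood at 0.23. Sftpc UMIs were found in 93.4% and 99.8% of thinned AT2-like cells and in 18.5% and 82.8% of thinned pericyte-like cells, so control droplets carried more free Sftpc RNA. Sftpc took 5.99% of AT2-like UMIs in the ablation library and 16.9% in control, and the median over all 13799 measured genes was 0.24, against −0.061 with median-of-ratios scaling, under which the AT2 identity median was −0.22. AT1 identity genes had a median of 0.25 (5 of 17 higher, 1 lower, percentile 41.5), with Pdpn at 2.33, Spock2 at 1.26, Hopx at 0.83 and Ager at 0.31. Without the cells low in AT2 markers that median was −1.12 and Hopx stood at −2.23. Club identity genes had a median of −0.78 (2 of 10 higher, 5 lower, percentile 0.080), with Scgb3a2 at −4.40, and the median was 0.55 with the loose filter and 1.62 with the libraries clustered apart.

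Of the other lists in AT2-like cells, translation factors were higher in 8 of 14 cases (median 0.73, percentile 98.0, and 0.27 thinned), macrophage phagocytosis in 9 of 17 (0.64, 91.9) and cytoskeleton and adhesion in 7 of 19 (0.51, 85.1). The macrophage phagocytosis median was −0.0091 without cells that carried another compartment's markers. Hypoxia and glycolysis genes were higher in 6 of 14 cases (0.48, percentile 80.2), capillary repair in 4 of 11 (0.22, 67.3), EGF family ligands in 2 of 6 (0.43, 63.0), cholesterol synthesis in 4 of 15 (0.31, 59.1), alveolar niche factors in 6 of 16 (0.28, 57.5) and NF-kB inflammation in 7 of 16 (0.31, 56.8). Matrix and fibrosis genes were higher in 4 of 18 cases (0.13, percentile 22.5), YAP TEAD targets in 2 of 13 (0.071, 20.3), Wnt in 3 of 13 (−0.13, 17.0), Notch in 2 of 10 (−0.16, 14.1) and surfactant lipid synthesis in 3 of 18 (0.065, 9.89). In the last list Elovl1, a fatty acid elongase gene, was highest (1.04) and Gpam, of glycerolipid synthesis, lowest (−1.21).

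**Figure D2:**
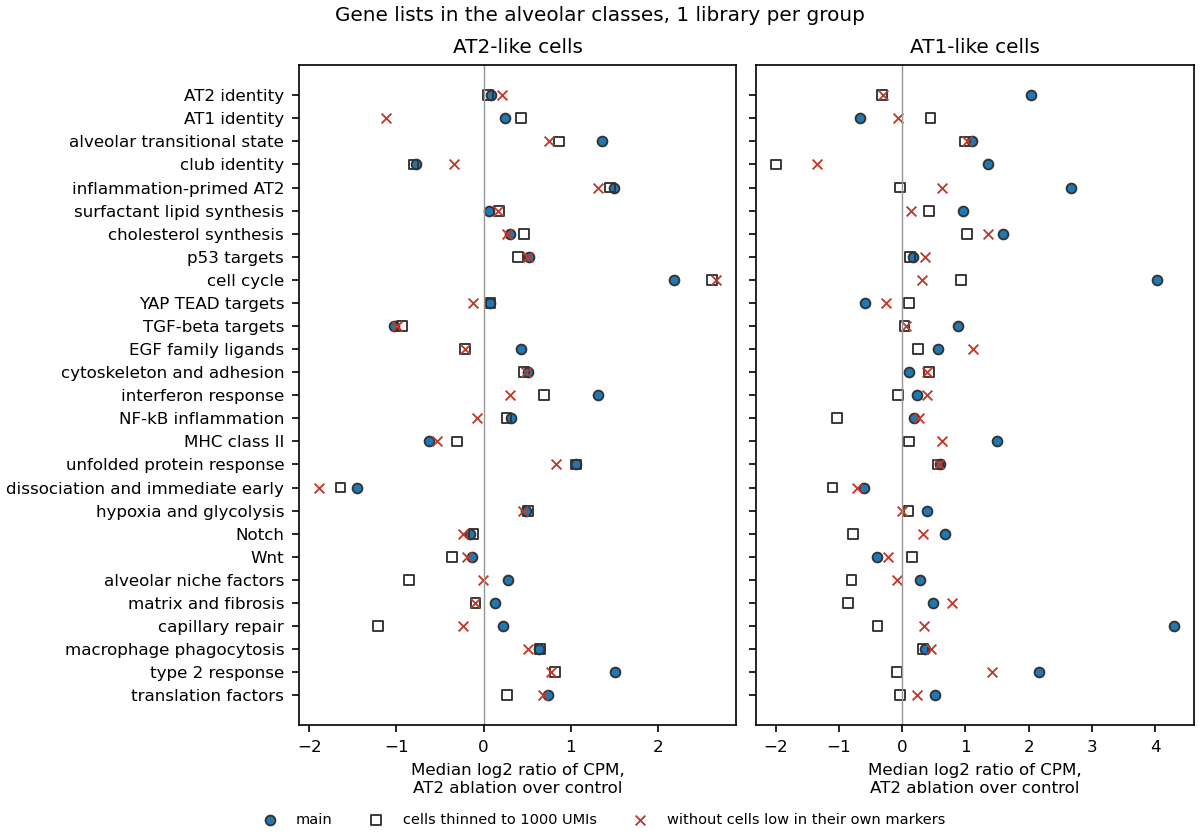
Median log2 ratio (ablation over control) of the 27 gene lists in AT2-like and AT1-like cells. Points give the main setting, thinned cells, and the class without cells low in its own markers. Under the main setting cell cycle stood at 2.18 and immediate early genes at −1.45 in AT2-like cells, and cholesterol synthesis at 1.60 in AT1-like cells.

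Among single genes picked by size in AT2-like cells, Dmkn (ENSMUSG00000060962, chromosome 7, 30763756 to 30781063), an epidermal secreted protein gene, stood at 666 against 53.9 CPM (3.63 [3.51, 3.74]). Kng2 (ENSMUSG00000060459, chromosome 16, 22985854 to 23029482), a kininogen gene, stood at 56.5 against 0.598 CPM (6.56 [5.61, 7.71]), and Phgr1 at 173 against 19.8 CPM (3.13). Krt19 stood at 448 against 64.5 CPM (2.79) and S100a6 at 2045 against 253 CPM (3.02), but without the cells low in AT2 markers at 1.55 and 0.73, and neither was then among the 10 highest. The other 5 of the 10 highest were Gsto1 (8.09), Pglyrp1 (5.58), Plet1 (5.09), Ecm1 (4.96) and Isg15 (5.46). Of their ablation UMIs 2 cells held 53.4% for Gsto1, 61.6% for Pglyrp1, 60.05% for Plet1, 64.1% for Ecm1 and 86.6% for Isg15. Without the cells low in AT2 markers Gsto1 stood at −0.0015, Plet1 at −0.23 and Ecm1 at −0.47, whereas Dmkn stood at 3.75, Kng2 at 6.65 and Phgr1 at 3.11. Under that alternative the 10 highest also took in Bcl2l15 (47.5 against 0.468 CPM, 6.67), the histone gene Hist1h4i (5.997) and Ptprn (5.03). The lowest gene was the clock gene Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665), at 4.64 against 81.1 CPM (−4.13 [−4.89, −3.46]). It was followed by Cbr2, a carbonyl reductase gene, at 780 against 4573 CPM (−2.55), Gem (−2.83), Aox3 (−2.58), Trib1 (−2.18), the nuclear RNA Neat1 at 780 against 3019 CPM (−1.95), Snhg11 (−2.14), Sec14l4 (−2.23), the insulin receptor substrate gene Irs2 (−1.97) and Sord (−2.04). The AT2-like class was cluster 1 of the epithelial clustering in the ablation library (204 of 212 cells) and cluster 2 in control (482 of 488), with medians of 15754 and 30570.5 UMIs per cell.

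In AT1-like cells, cholesterol synthesis and transitional genes were higher in the ablation library under each alternative that gave a value. Cholesterol synthesis genes were higher in 13 of 15 cases, with a median of 1.60 [0.80, 2.05], percentile 100 (1.03 thinned, 1.36 without cells low in AT1 markers). Sqle, which makes squalene epoxide, stood at 36.5 against 6.80 CPM (2.42 [1.79, 3.05]), while Sc5d (−0.030) and Lss (0.41) were lowest. Transitional genes were higher in 11 of 16 cases (median 1.10 [0.51, 2.07], percentile 100, and 0.996 thinned). Sprr1a stood at 95.3 against 1.09 CPM (6.45 [5.42, 7.70]), Sfn, the 14-3-3 sigma gene, at 138 against 23.5 CPM (2.55 [2.23, 2.87]), Krt8 at 1178 against 500.5 CPM (1.23 [1.14, 1.33]) and Krt7 at −0.88. Unfolded protein response genes were higher in 7 of 13 cases (0.61, percentile 99.7, and 0.57 thinned), with Manf at 1.56 and Sdf2l1 at 1.48. Immediate early genes were lower in 9 of 18 cases and higher in 3 (−0.61 [−1.37, 0.39], percentile 0.61, and −1.10 thinned), with Fosb at −1.97.

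Several other AT1-like values were nearer 0 or of opposite sign without 12 ablation cells low in AT1 markers, which held 35.9% of the UMIs of the class (20 such control cells held 2.396%), or after thinning. With them, AT2 identity genes had a median of 2.04 [1.03, 2.80] (14 of 14 higher, percentile 100), AT1 identity −0.66 [−1.02, −0.32] (9 of 17 lower, percentile 0.750), club identity 1.36 (8 of 10 higher) and inflammation-primed genes 2.66 (10 of 10 higher). Without them these medians were −0.30, −0.066, −1.34 and 0.63, and after thinning −0.32, 0.45, −1.99 and −0.028. Cell cycle genes went from 4.03 (18 of 18 higher) to 0.32 and 0.93, capillary repair from 4.30 (11 of 14 higher) to 0.35 and −0.39, TGF-beta targets from 0.88 (8 of 13 higher) to 0.064 and 0.039, MHC class II from 1.502 (6 of 6 higher) to 0.64 and 0.11, type 2 response from 2.17 (6 of 6 higher) to 1.42 and −0.082, and surfactant lipid synthesis from 0.96 (12 of 18 higher) to 0.14 and 0.42. Sftpc stood at 12374 against 6482 CPM (0.93) with these cells, at −1.17 without them and at −1.74 thinned. Hopx stood at −1.24 (2273 against 5384 CPM), −0.66 and −0.53, and Ager went from −0.22 to 0.35 and 0.59. AT2 identity and club identity had the opposite sign in AT1-like cells under all 8 alternatives that clustered the cells again (AT2 identity from −3.67 to −2.24, club identity from −1.90 to −1.17), so none of the values in this paragraph is read as a difference between AT1 cells. Type 2 response, MHC class II and inflammation-primed genes stayed beyond 1.5-fold without the 12 cells but not after thinning.

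The remaining lists in AT1-like cells had medians of 0.67 for Notch (5 of 10 higher, percentile 96.6), 0.57 for EGF family ligands (2 of 5, 96.2), 0.53 for translation factors (5 of 14, 99.1), 0.50 for matrix and fibrosis (8 of 18, 99.97), 0.40 for hypoxia and glycolysis (6 of 14, 97.48) and 0.37 for macrophage phagocytosis (5 of 14, 95.7). Alveolar niche factors stood at 0.28 (6 of 16, 85.5), interferon response at 0.24 (5 of 15, 95.4), NF-kB inflammation at 0.19 (4 of 13, 84.3), p53 targets at 0.18 (5 of 15, 93.9), cytoskeleton and adhesion at 0.11 (6 of 19, 76.1), Wnt at −0.40 (1 of 11, 10.8) and YAP TEAD targets at −0.59 (3 of 13, 1.46). Among the 8 alternatives that clustered the cells again, Notch stood below 0 in 7, matrix, alveolar niche factors (down to −1.27), NF-kB inflammation (−1.62) and macrophage phagocytosis (−0.64) in all 8, and hypoxia and glycolysis (−0.10) in 6. After thinning the medians of Notch, matrix and YAP TEAD targets were −0.77, −0.85 and 0.10. The YAP targets Ccn2 (−1.71 [−1.93, −1.50]) and Ccn1 (−1.64 [−1.79, −1.50]), genes of matricellular proteins, were lowest in their list and stood at −0.81 and −0.92 thinned.

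The 10 highest genes by size in AT1-like cells included Poc1a (ENSMUSG00000023345, chromosome 9, 106281061 to 106350521), a centriole protein gene, at 745 [696, 797] against 42.6 [38.0, 47.6] CPM (4.13), Msln (ENSMUSG00000063011, chromosome 17, 25748613 to 25754378), the mesothelin gene, at 391.8 against 19.2 CPM (4.35 [4.07, 4.64]), and Phgr1 at 168 against 13.1 CPM (3.69). Without cells low in AT1 markers these stood at 4.74, 4.97 and 4.05. The other 7 were airway and AT2 genes, namely Scgb1a1 (12.79), Scgb3a1 (5.68), Lcn2 (4.19), Cxcl15 (3.21), Retnla (3.05), Napsa (2.95) and Sftpd (2.80). Of their ablation UMIs 2 cells held 98.5% for Scgb1a1 and 99.5% for Scgb3a1, and 6 of the 7, all but Scgb1a1, had the opposite sign under each of the 8 alternatives that clustered the cells again. Cd59a (237 against 26.9 CPM, 3.14), Osbpl3 (3.59), Sfn (2.82) and Qsox1 (2.49) entered the 10 highest once cells low in AT1 markers were left out. Lowest were Per3 (−2.79), Plscr2 (−2.47), Cavin2, of caveolae, at 520 against 2368 CPM (−2.19), Bdnf (−2.24), Rusc2 (−2.40), Scel (−2.41), Dusp7 (−2.18), Tent5b (−2.48), and the cell polarity genes Mpp5 (−2.10) and Pard6b (−2.05). Each of these 10 was also lower after thinning, from −0.76 for Bdnf to −2.24 for Tent5b. Without cells low in AT1 markers Per3, Plscr2, Rusc2, Cavin2 and Dusp7 stayed among the 10 lowest. Bdnf, Scel, Tent5b, Mpp5 and Pard6b then gave way to Pttg1, Eif3j2, Rspo1, Tln2 and Hist1h4d. AT1-like cells were cluster 3 in the ablation library (191 of 199, median 2499 UMIs). In control they were clusters 8 (577 of 912, median 1667 UMIs) and 11 (335, median 16256 UMIs).

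The 40 transitional-like cells came from the ablation library alone, as epithelial cluster 9, and have no control cells to compare with. The values of the genes that named them are not results. Of the 16 transitional markers only Sprr1a was among the 10 top genes of the cluster, and Krt8 (875 against 1178 CPM), Sfn (5.77 against 138 CPM), Itgb6 (88.1 against 387 CPM), Hbegf (180.5 against 792 CPM) and Plaur (18.8 against 62.3 CPM) were lower than in AT1-like ablation cells. F3 (ENSMUSG00000028128, chromosome 3, 121723537 to 121735048), the tissue factor gene, which is also among the genes that set this cluster apart, stood at 6109 [5927, 6296] CPM, against 43.3 CPM in AT2-like and 353 CPM in AT1-like ablation cells, and it and Gdf15 were picked after their values were seen. Cdkn1a stood at 2454 CPM against 215 and 231 CPM, and Gdf15, a stress-induced p53 target, at 664 CPM against 21.9 and 9.79 CPM. Sftpc stood at 22225 CPM, against 59927 CPM in AT2-like cells, Hopx at 143 CPM against 188 and 2273 CPM, and Ager at 440 CPM against 1248 and 10636 CPM. Hopx and Ager were thus below AT2-like cells as well, so these genes do not place the cells between AT2-like and AT1-like cells. The AT1-like reference values include the 12 cells low in AT1 markers. Mki67 had 2 UMIs (2.89 CPM [0.350, 10.4]), and 20 of 40 thinned cells, [33.8%, 66.2%], held a UMI of the cell cycle list, and 4 of 40 held at least 2, 10.0% [2.79, 23.7]. For comparison, 33.5% of ablation AT2-like and 9.01% of ablation pericyte-like cells held at least 1, and 16.5% and 1.05% at least 2.

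In ciliated-like cells the acute-phase glycoprotein genes Orm2 and Orm1 were among the 5 highest by size, at 301 against 1.15 CPM (8.04) and 437 against 13.2 CPM (5.05). Thinned shares of cells with a UMI were 15.4% and 0 for Orm2 and 27.8% and 0.694% for Orm1, against at most 0.253% of pericyte-like cells. Reg3g, an antimicrobial lectin gene that also ranks among the top genes of the club-like clusters, stood at 681 against 49.6 CPM (3.78), with 90.2% of its control UMIs in 2 cells and thinned shares of 9.83% and 0.694%, against 0.601% and 1.52% of pericyte-like cells. The inflammation-primed list had 5 of 10 members higher and 2 lower (median 1.46). The secretoglobin genes Scgb1a1 and Scgb3a1 were the highest of all. Scgb1a1 made up 3.07% of ablation UMIs in ciliated-like cells, where 2 cells held 41.0% of them, against 0.145% in pericyte-like and 0.0228% in mesothelial-like cells, and was found in 78.2% of thinned ciliated-like and 62.6% of thinned pericyte-like cells. Lower were Chia1 (−3.62, with 89.8% of its control UMIs in 2 cells), Esm1 (−3.23), Areg at 111 against 541 CPM (−2.28), Jun at 838 against 3095 CPM (−1.89) and Gstp1 (−2.02). Club or secretory-like cells differed in Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), the main secretory protein gene of club cells, at 525391 CPM in the ablation library and 203 CPM in control. As this gene took 52.5% and 0.0203% of the UMIs of the class, the median over all measured genes there was −1.06, and other club-like ratios are relative to that. The estrogen receptor gene Esr1 had 1 ablation UMI (0.535 against 308 CPM, −9.17 [−14.47, −6.69]), Cyp2a5 stood at −4.02, Slc7a11 at −4.74, Ifrd1 at −3.33 and Atf3 at −2.86, and Calca, Orm1, Resp18 and Upk3a were higher (137, 30.0, 140.0 and 45.5 CPM against 24.8, 3.04, 39.5 and 9.88 CPM). Calca and Resp18 belong to the neuroendocrine marker set, whose name no cluster earned, so neuroendocrine cells within the club-like class are not excluded. The club-like class was cluster 0 in the ablation library and in control cluster 0 (62 of 248 cells), which held 82.5% of the UMIs summed here, and cluster 12 (186 cells, median 1399.5 UMIs), and ciliated-like cells were clusters 4 (222 of 234) and 7 (138 of 144).

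Among stromal and mesothelial cells the fibroblast classes are those left by different depletions. The highest genes by size in adventitial fibroblast-like cells were the chemokine gene Ccl8 (269.5 against 20.7 CPM, 3.70), the acute-phase gene Saa3 (805 against 114 CPM, 2.82), Prg4 (3.60), Chl1 (5.51) and the protease inhibitor gene Timp1 (1883 against 289 CPM, 2.70). Timp1 was also higher in myofibroblast-like cells (918 against 105 CPM, 3.13), with Spon2 (3.80), the EGF family gene Ereg (3.17) and Gbp2b (34.6 against 0 CPM, at least 18.8-fold). Pericyte-like cells had more Spon2 (3.29), Fst, which encodes the activin inhibitor follistatin, at 1572 against 251 CPM (2.65), Gdpd3 (5.69 [4.09, 7.99], 3 control UMIs) and Hspa1b (2.43), and less Ccl19 (−6.82 [−9.10, −5.26], 3 ablation UMIs), Eln (−3.51) and Col18a1 (−4.43). In smooth muscle-like cells elastin was the other way, at 2914 against 575 CPM (2.34), along with Col8a1 (3.60), Fst (3.03) and Trpc6 (3.74), and Retnla (341 against 18.2 CPM) had 92.7% of its ablation UMIs in 2 cells. Mesothelial-like cells had more Il18r1 (875 against 122 CPM, 2.84), Fgfbp1 (3.32) and Gbp2b (147 against 0 CPM, at least 131-fold), and Top2a (142 against 3.74 CPM) had 63.8% of its ablation UMIs in 2 cells. Also lower were Ccl19 in adventitial fibroblast-like (−2.87) and myofibroblast-like cells (−7.02), Nr4a2 in adventitial fibroblast-like (−2.49) and pericyte-like cells (−3.70), Tcap in myofibroblast-like (−4.73) and smooth muscle-like cells (−3.25), Pnmt (−3.03) and Tex15 (−4.56) in myofibroblast-like cells, Stbd1 (−4.21) in smooth muscle-like cells, and Fosb (−3.32), Atf3 (−2.99) and Egr1 (−2.94) in mesothelial-like cells.

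Across these classes the unfolded protein response list was higher, with medians of 0.91 in adventitial fibroblast-like (9 of 13 members), 0.68 in ciliated-like (7 of 13), 1.11 in mesothelial-like (9 of 14), 0.73 in myofibroblast-like (8 of 13), 0.69 in pericyte-like (8 of 13) and 0.82 in smooth muscle-like cells (7 of 12). In club-like cells it was −0.79, and 0.20 with median-of-ratios scaling. Immediate early genes were lower, at −1.22 in adventitial fibroblast-like, −1.36 in ciliated-like, −1.30 in mesothelial-like, −1.69 in pericyte-like, −1.41 in smooth muscle-like and −1.98 in club-like cells (−0.99 with median-of-ratios scaling), but −0.23 in myofibroblast-like cells, under the size called lower. Cholesterol synthesis stood at 1.52 in pericyte-like (14 of 15 higher, 1.46 thinned), 1.09 in myofibroblast-like, 0.93 in mesothelial-like, 0.91 in smooth muscle-like and 0.51 in adventitial fibroblast-like cells, but thinned at 0.35, −0.22 and 0.37 in myofibroblast-like, mesothelial-like and smooth muscle-like cells. It stood at −0.31 in ciliated-like and −0.84 in club-like cells (0.15 with median-of-ratios scaling). Matrix genes stood at 1.16 in smooth muscle-like (13 of 17 higher), 0.75 in mesothelial-like, 0.46 in adventitial fibroblast-like, −0.024 in myofibroblast-like, −0.37 in pericyte-like, −1.41 in ciliated-like and −3.05 in club-like cells. Over the alternatives these ran from 0.21 to 1.33 in smooth muscle-like, −0.54 to 0.22 in pericyte-like, −2.68 to −0.34 in ciliated-like and −3.67 to −0.49 in club-like cells. Alveolar fibroblast-like cells numbered 15 in the ablation library and 3155 in control. Unnamed clusters 0 (932 ablation and 8 control cells) and 10 (710 and 1) were also closest to alveolar fibroblasts. Which library held more free fibroblast RNA was not measured. Such RNA in ciliated-like and club-like droplets therefore cannot be told apart from expression by the airway cells. Adventitial fibroblast-like (cluster 20), mesothelial-like (24) and smooth muscle-like cells (27) shared a cluster between libraries, while myofibroblast-like cells were clusters 6 (1085) and 32 (144 of 155) and pericyte-like cells clusters 14 (660 of 666) and 30 (394 of 396).

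**Figure D3:**
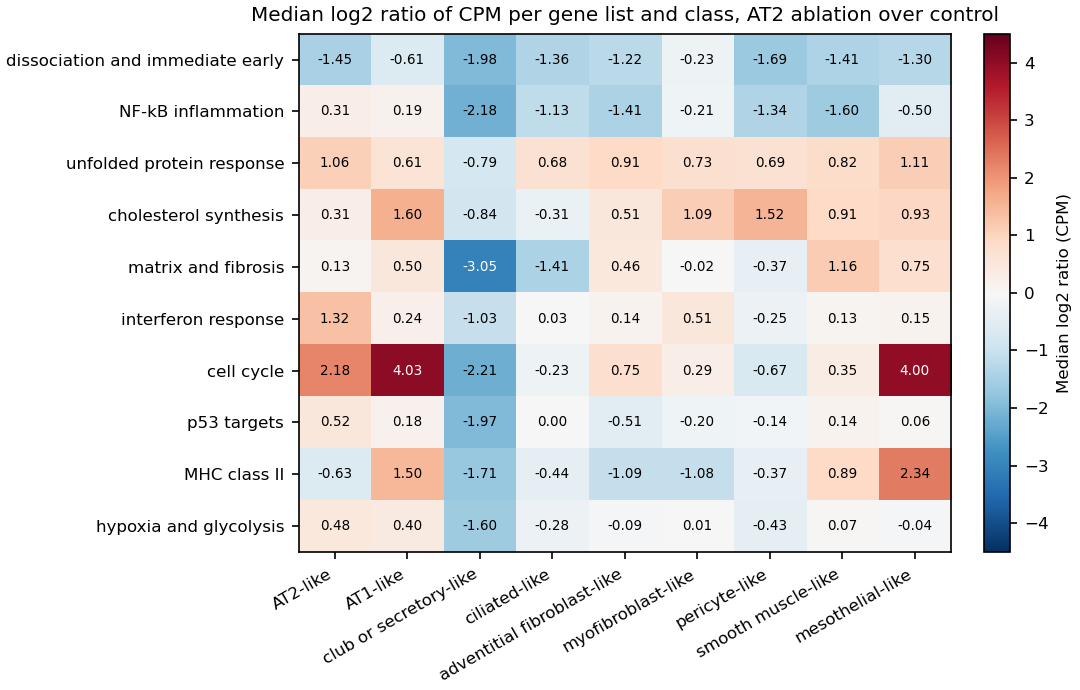
Median log2 ratio (ablation over control) of 10 gene lists (vertical) in each of the 9 compared cell classes (horizontal), as colour and number. Unfolded protein response genes were above 0 in all classes but the club-like one, and immediate early genes were below 0 in all of them.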

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

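All tests of explanations in this part were chosen after the results were seen. Club identity genes had opposite median log2 ratios in the 2 alveolar classes, −0.78 in AT2-like and 1.36 in AT1-like cells, as did TGF-beta targets, −1.03 and 0.88, and MHC class II genes, −0.63 and 1.502. What singled them out is that the 2 classes went opposite ways, and this difference was not tested. Without 12 ablation cells low in AT1 markers the AT1-like values were −1.34, 0.064 and 0.64, so that only MHC class II stayed opposite by size, and after thinning it stood at 0.11. Among cells that earned no name, cluster 0 made up 9.35% [8.78, 9.94] of kept ablation cells and 0.128% of control cells, with Saa3, Saa1, Timp1, Chl1 and Tnc as its top genes and the alveolar fibroblast set as the closest. Cluster 1 made up 8.28% [7.75, 8.84] and 1.397%, with Lamc3, Adh7 and Dner and the adventitial fibroblast set closest, and cluster 10 made up 7.12% [6.62, 7.64] and 0.0161%, with Adamts15, Cacna1d and Vipr2 and the alveolar fibroblast set closest. Cluster 21, with Il1b, Il1r2 and Csf3r beside Vwf and Ptprb, made up 1.27% [1.06, 1.51] and 0 of 6228 control cells, which allows a share of up to 0.0482%. These clusters were singled out because they enter no comparison of expression or of epithelial composition, and each is above its level in control. The depletions differed between the libraries, and these differences were not tested.

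Under the main setting AT2-like cells made up as large a share of epithelial cells after ablation as in control, although the transgene is aimed at them. Per ciliated-like cell they were fewer, at 0.906 [0.749, 1.10] against 3.39 [2.81, 4.11], but not with the loose filter (0.850 against 0.145). Per club-like cell they were more, at 3.07 against 1.97, but 2.49 against 7.94 under the strict filter. Their share was 24.8% against 9.40% with the loose filter. Without cells that carried another compartment's markers, a rule that removed most alveolar cells, it was 40.2% against 90.6%. Under the strict cell filter, which removes low-UMI barcodes, the share was 32.5% [28.6, 36.7] (174 of 535) against 37.6% [34.8, 40.5] (429 of 1141), 5.08 points lower with overlapping intervals, so a part of such barcodes in the control denominator cannot be told apart from no part. AT1-like cells stood at 0.850 per ciliated-like cell against 6.33 in control, which is what a denominator short of AT1-like cells needs, although the loose filter gave 1.21 against 0.386. Both counts enter the epithelial shares, so this ratio restates them and is no separate test. Of thinned ablation AT2-like cells 33.5% held a cell cycle UMI, which is what division of AT2 cells between the doses and collection needs. Both stay open, as does incomplete recombination, which was not tested.

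Genes that oscillate with Dbp, the clock output gene, were lower in the ablation library in 9 of 9 classes, with medians from −3.27 to −0.77. Lungs collected at different times of day would also set antiphase genes such as Arntl higher, and 7 of 9 classes had the medians in opposite directions, but with 1 library per group time of collection cannot be told apart from the treatment. A response confined to alveolar epithelial cells is argued against by the stromal and mesothelial classes, whose in-phase median was −2.96 against −2.88 in the alveolar classes. Free RNA from 1 source would spread Dbp evenly, and the highest class of the control library had 2.72 times the Dbp of the lowest (320 [298, 342] against 118 [110, 126] CPM), which decides nothing because both background and clock RNA are found in every class. A response of the whole lung to the ablation stays open and was not tested.

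Scgb1a1, the most abundant transcript of ablation club-like cells, was nearly absent from the control library. Low-UMI barcodes are argued against as the reason, since in epithelial cluster 0, which holds 69 ablation and 62 control cells, Scgb1a1 stood at 525391 against 235 [219, 253] CPM, 2232-fold higher. Whether the control class holds cells without club identity cannot be told, since 8 of the 9 other measured members of the club list (median −0.70) belong to the markers that named the class. A single pooled animal without the transcript is argued against, since control cells of that cluster with only Xist UMIs (10 cells, 390.0 [331, 457] CPM) and with only Y-linked UMIs (33 cells, 217 [197, 238] CPM) were both far below the ablation library. Reads left uncounted in 1 library and a genotype difference between the mice were not tested. Esr1 ranked lowest by size in ablation club-like cells, the opposite direction to Scgb1a1, and a link between these genes was not tested.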

How the results depend on the processing

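No paired analysis was possible because each group has 1 library, and no replicate could be left out. Depth limits gene values to those with at least 10 UMIs over both libraries in lists, 50 UMIs in named genes, and AT1-like cells were shallow, with medians of 2386 UMIs per cell in the ablation library and 2712 in control. The control AT1-like cells were uneven in depth, with medians of 1667 UMIs in epithelial cluster 8 and 16256 in cluster 11. Alternatives were fixed before the data were examined except 5 that were chosen after seeing the data, namely scrublet's automatic threshold in each library, the removal of cells low in their own markers, the removal of cells that carry another compartment's markers, the removal of control cells with a Xist UMI, and totals without Scgb1a1. Results of at least 1.5-fold that kept their sign under every alternative that gave a value were 9 of 12 lists and 20 of 25 genes in the AT2-like class, and 4 of 16 lists and 18 of 26 genes in the AT1-like class. In the other classes 2 of 2 lists kept it in adventitial fibroblast-like, 3 of 3 in ciliated-like, 2 of 4 in club or secretory-like, 3 of 4 in mesothelial-like, 2 of 2 in myofibroblast-like, 3 of 3 in pericyte-like and 4 of 4 in smooth muscle-like cells. Of 432 AT2-like list values under alternatives, 388 lay within the interval of the main value, 35 lay outside it with the sign kept or a main value under 1.5-fold, and 9 of at least 1.5-fold changed sign, and the same counts in AT1-like cells were 285, 51 and 69 of 405. In AT2-like cells the cell cycle median ran from 1.76 to 5.88 over 16 alternatives, the transitional median from 0.75 to 1.45, the inflammation-primed median from 1.20 to 1.61, the unfolded protein response median from 0.76 to 1.14, the interferon median from 0.047 to 1.99 and the immediate early median from −2.01 to −1.10. In AT1-like cells the transitional median ran from 0.94 to 1.17 and the cholesterol synthesis median from 1.03 to 1.76 over 15 alternatives. Pseudocounts of 1 and 50 CPM named 10 and 16 of the same 20 AT2-like genes and 10 and 14 of the same 20 AT1-like genes, and a detection minimum of 5% of cells named 19 and 17.

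No value came from the club or secretory-like class under coarser clusters (68 ablation and 16 control cells), finer clusters (68 and 45) or the loose filter (78 and 27), nor from the pericyte-like class under coarser clusters (668 and 2). The removal of cells that carry another compartment's markers left under 50 cells in at least 1 library in all classes but the AT2-like one, among them the AT1-like class with 29 and 8. List and gene values given here are log2 ratios, ablation over control, and shares are of epithelial cells. The main values in AT1-like cells were 2.04 for AT2 identity, −0.66 for AT1 identity, 1.36 for club identity, 2.66 for inflammation-primed AT2, 4.03 for cell cycle, 0.88 for TGF-beta targets, 0.67 for Notch and 4.30 for capillary repair, and 5.68 for Scgb3a1, 4.19 for Lcn2, 3.21 for Cxcl15, 2.95 for Napsa, 3.05 for Retnla, 2.80 for Sftpd, 0.93 for Sftpc and 2.20 for Sftpb. For each value that moved or changed sign under an alternative, the cause was not tested, unless stated with it.

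With the loose cell filter, the AT2-like share was 24.8% in the ablation library and 9.40% in control and the AT1-like share was 35.3% in the ablation library and 25.1% in control. The AT1-like list medians were −2.64 for AT2 identity, 0.018 for AT1 identity, −1.51 for club identity, −0.85 for inflammation-primed AT2, −0.032 for surfactant lipid synthesis and −0.22 for capillary repair. Log2 ratios of AT1-like genes were −0.93 for Scgb3a1, −2.05 for Lcn2, −2.24 for Cxcl15, −0.68 for Napsa, −0.89 for Retnla, −2.68 for Sftpd, −4.12 for Sftpc and −2.98 for Sftpb. AT2-like values were 0.55 for club identity, 2.88 for cell cycle and 0.20 for TGF-beta targets. Elsewhere the medians were −2.68 for matrix in the ciliated-like class and 0.62 for matrix in the smooth muscle-like class. Under the strict cell filter, the AT2-like share was 32.5% in the ablation library and 37.6% in control and the AT1-like share was 17.9% in the ablation library and 47.5% in control. Medians of lists in the AT1-like class were −3.08 for AT2 identity, 0.031 for AT1 identity, −1.17 for club identity, −0.66 for inflammation-primed AT2, −0.56 for TGF-beta targets, −0.13 for Notch and −0.35 for capillary repair. The AT1-like genes stood at −0.88 for Scgb3a1, −4.03 for Lcn2, −3.23 for Cxcl15, −0.024 for Napsa, −0.44 for Retnla, −2.56 for Sftpd, −5.04 for Sftpc and −3.64 for Sftpb. Plet1 was at −0.20 in AT2-like cells. Other classes gave −0.67 for matrix in the ciliated-like class, −0.30 for unfolded protein response in the club or secretory-like class, −0.49 for matrix in the club or secretory-like class and 0.21 for matrix in the smooth muscle-like class. When doublet calls were kept, the AT2-like share was 32.5% in the ablation library and 35.5% in control and the AT1-like share was 22.8% in the ablation library and 54.4% in control. AT1-like medians stood at −3.27 for AT2 identity, 0.15 for AT1 identity, −1.74 for club identity, −1.04 for inflammation-primed AT2, −0.089 for cell cycle, −0.34 for TGF-beta targets, −1.43 for immediate early, −0.36 for Notch and −0.49 for capillary repair. In the same class the gene values were −1.88 for Scgb3a1, −2.23 for Lcn2, −2.60 for Cxcl15, −0.42 for Napsa, −0.77 for Retnla, −2.67 for Sftpd, −4.84 for Sftpc and −3.32 for Sftpb. In AT2-like cells the values were 0.054 for club identity, −0.16 for Plet1, −0.32 for Ecm1 and −0.97 for Hopx. Among other classes the medians were −0.70 for matrix in the ciliated-like class and −1.02 for matrix in the club or secretory-like class.

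With finer clusters, the AT2-like share was 22.9% in the ablation library and the AT1-like share was 62.6% in control. The AT1-like list medians were −3.67 for AT2 identity, 0.15 for AT1 identity, −1.90 for club identity, −1.22 for inflammation-primed AT2, −0.19 for TGF-beta targets, −0.043 for MHC class II, −1.46 for immediate early, −0.43 for Notch and −0.54 for capillary repair. Log2 ratios of AT1-like genes were −1.88 for Scgb3a1, −2.41 for Lcn2, −3.07 for Cxcl15, −0.63 for Napsa, −0.87 for Retnla, −3.10 for Sftpd, −5.11 for Sftpc and −3.81 for Sftpb. AT2-like values were −0.19 for Gsto1, −0.14 for Ecm1, −1.54 for Hopx and −0.16 for Mki67. Elsewhere the medians were −0.78 for matrix in the ciliated-like class and 0.60 for matrix in the smooth muscle-like class. After each library was clustered on its own, the AT2-like share was 31.9% in the ablation library and 30.3% in control and the AT1-like share was 56.6% in control. Medians of lists in the AT1-like class were −3.48 for AT2 identity, 0.076 for AT1 identity, −1.55 for club identity, −0.96 for inflammation-primed AT2, −0.10 for cell cycle, −0.043 for TGF-beta targets, −0.34 for Notch and −0.27 for capillary repair. The AT1-like genes stood at −1.31 for Scgb3a1, −1.97 for Lcn2, −2.85 for Cxcl15, −0.50 for Napsa, −0.24 for Retnla, −2.91 for Sftpd, −5.00 for Sftpc and −3.49 for Sftpb. The AT2-like class gave 1.62 for club identity, 5.88 for cell cycle and 0.17 for TGF-beta targets. Other classes gave −0.16 for unfolded protein response in the club or secretory-like class, −3.67 for matrix in the club or secretory-like class, 1.22 for cholesterol synthesis in the pericyte-like class, 0.22 for matrix in the pericyte-like class and 0.39 for matrix in the smooth muscle-like class. With coarser clusters, the AT2-like share was 32.5% in control and the AT1-like share was 58.7% in control. AT1-like medians stood at −3.38 for AT2 identity, 0.093 for AT1 identity, −1.73 for club identity, −1.08 for inflammation-primed AT2, −0.034 for TGF-beta targets, −0.38 for Notch and −0.29 for capillary repair. In the same class the gene values were −1.49 for Scgb3a1, −2.06 for Lcn2, −2.85 for Cxcl15, −0.42 for Napsa, −0.47 for Retnla, −2.87 for Sftpd, −4.96 for Sftpc and −3.71 for Sftpb. In AT2-like cells the values were 0.80 for club identity and 0.069 for TGF-beta targets. Among other classes the medians were 1.05 for cholesterol synthesis in the adventitial fibroblast-like class, −0.75 for matrix in the ciliated-like class and 0.50 for matrix in the smooth muscle-like class. Clustering without the genes of the alveolar lists moved neither the AT2-like nor the AT1-like shares. There the AT1-like list medians were −2.24 for AT2 identity, 0.059 for AT1 identity, −1.64 for club identity, −0.80 for inflammation-primed AT2, −0.37 for TGF-beta targets, −0.41 for Notch and −0.31 for capillary repair. Log2 ratios of AT1-like genes were −1.31 for Scgb3a1, −2.08 for Lcn2, −2.21 for Cxcl15, −0.35 for Napsa, −0.45 for Retnla, −1.46 for Sftpd, −4.10 for Sftpc and −2.21 for Sftpb. Plet1 stood at −0.16 in AT2-like cells, and the matrix median was −0.34 in the ciliated-like class.

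After thinning of every cell to 1000 UMIs, medians of lists in the AT1-like class were −0.32 for AT2 identity, 0.45 for AT1 identity, −1.99 for club identity, −0.028 for inflammation-primed AT2, 0.10 for YAP TEAD targets, −0.77 for Notch, −0.39 for capillary repair and −0.082 for type 2 response. The AT1-like genes stood at −0.082 for Retnla, −1.74 for Sftpc and −0.45 for Sftpb. Other classes gave −2.05 for matrix in the ciliated-like class, −1.22 for unfolded protein response in the club or secretory-like class, −0.22 for cholesterol synthesis in the mesothelial-like class, 0.35 for cholesterol synthesis in the myofibroblast-like class and 0.37 for cholesterol synthesis in the smooth muscle-like class. Under median-of-ratios scaling, the AT2 identity median in AT2-like cells was −0.22. Among other classes the medians were −0.99 for immediate early, 0.15 for cholesterol synthesis and 0.20 for unfolded protein response, each in the club or secretory-like class.

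With scrublet's automatic threshold in each library, the AT1-like list medians were −3.41 for AT2 identity, 0.070 for AT1 identity, −1.66 for club identity, −1.16 for inflammation-primed AT2, −0.017 for cell cycle, −0.060 for TGF-beta targets, −0.41 for Notch and −0.29 for capillary repair. Log2 ratios of AT1-like genes were −1.30 for Scgb3a1, −2.12 for Lcn2, −2.80 for Cxcl15, −0.53 for Napsa, −0.48 for Retnla, −2.93 for Sftpd, −5.00 for Sftpc and −3.58 for Sftpb. Club identity stood at 0.16 in AT2-like cells, and the matrix median was −0.41 in the ciliated-like class. Without cells low in the markers of their own class, medians of lists in the AT1-like class were −0.30 for AT2 identity, −0.066 for AT1 identity and −1.34 for club identity. The AT1-like genes stood at −1.40 for Scgb3a1, −0.28 for Retnla, −1.17 for Sftpc and −0.53 for Sftpb. The AT2-like class gave −0.0015 for Gsto1, −0.23 for Plet1, −0.47 for Ecm1 and −2.23 for Hopx. Without cells that carry another compartment's markers, the AT2-like share was 40.2% in the ablation library and 90.6% in control and the AT1-like share was 8.84% in the ablation library and 4.71% in control. In AT2-like cells the values were −0.0091 for macrophage phagocytosis, −0.86 for Ecm1 and −1.21 for Hopx. Without control cells that had a Xist UMI, the cell cycle median in AT2-like cells was 3.13. With totals counted without Scgb1a1, medians were −0.91 for immediate early, 0.23 for cholesterol synthesis, 0.28 for unfolded protein response and −1.97 for matrix, each in the club or secretory-like class. In the AT1-like class the removal of 12 ablation and 20 control cells low in their own markers took away 35.9% and 2.396% of the class's UMIs, which by construction is the cause of the values under that alternative. In the club or secretory-like class Scgb1a1 held 52.5% of the UMIs of the ablation library and 0.0203% of those of control, so that totals with it lower every other gene there by construction.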

Other observations

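Tests of explanations are in the first part of this section, and the clock genes below were picked after the results were seen. The circadian repressor and output genes were lower together in ablation AT2-like cells. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a transcription factor gene of clock output, stood at 1.81 against 161 CPM, a log2 ratio of −6.48 [−7.80, −5.44], Nr1d1, which encodes REV-ERB alpha, at 16.8 against 141 CPM (−3.07) and Nr1d2 at −3.30. Tef (−3.24), Per2 (−2.52) and Cry2 (−1.92) were lower too, and the activators Arntl (17.0 against 2.06 CPM, 3.05 [2.41, 3.71]) and Npas2 (4.36) were higher. The same genes stood apart in stromal cells. Dbp was at −5.56 in adventitial fibroblast-like, −5.99 in myofibroblast-like, −6.15 in pericyte-like, −5.496 in smooth muscle-like and −5.76 in mesothelial-like cells, with Arntl at 5.14, 3.82, 5.19, 4.19 and 3.98. Ciliated-like cells differed least, with Dbp at −1.26, Per2 at 0.073 and a median of −0.77 over 10 clock genes in phase with Dbp.

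Immune and endothelial cells were found mainly in the ablation library, which held CD45-depleted and undepleted cells. B or plasma cell-like cells numbered 323 and 10 (ablation and control), interstitial macrophage-like 526 and 1, neutrophil-like 482 and 0, T cell-like 449 and 0, alveolar macrophage-like 344 and 0, NK cell-like 215 and 1, dendritic cell-like 205 and 0, aerocyte-like 92 and 0, lymphatic endothelial-like 27 and 0 and mast cell-like 19 and 0. Erythroid-like cells numbered 75 and 12. In the epithelial clustering 2 clusters earned no name. Cluster 5 (39 ablation and 36 control cells) had the cartilage genes Cytl1, Snorc, Chad, Acan and Col2a1 on top, and cluster 6 held 15 and 9 cells.

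The libraries differed in the sex of the mice. Of kept ablation cells 6071 held only Y-linked UMIs, 6 only Xist, 11 both and 3882 neither, whereas control had 2707, 1216, 371 and 1934. Xist stood at 0.243 against 217 CPM over all kept cells, and Ddx3y at 98.4 against 96.8 CPM. The 371 control cells with both kinds of UMI are counted without correction for free RNA or doublets. Transitional-like cells had a median doublet score of 0.0774, which with unnamed epithelial cluster 5 was the highest of the 13 epithelial clusters. Median scores of the AT2-like clusters 1 and 2 were 0.0361 and 0.0334.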
